A study of Oryza sativa with 6 samples.

How the data were processed

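RNA sequencing was done on mature rice leaves collected 60 days after germination, from an SRL1 knockout (srl1-KO) and from a control without the knockout (non-KO), with 3 libraries per genotype. Plants were grown in a greenhouse at 30 °C by day and 25 °C by night, per the labels' protocols. Poly(A) RNA was selected from 1 µg of total RNA and made into Illumina libraries with a fragment size near 240 bp, per the labels' protocols. The protocol speaks of leaves from a single plant, and nothing in the labels says how the 3 libraries of a genotype relate to plants or growth batches. The p-values therefore measure the spread between these libraries, part or all of which may be technical or lie within 1 plant. They may not measure the spread between plants of a genotype.

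The deposited file holds FPKM values (fragments per kilobase of transcript scaled to the mapped fragments of the library), 1 column per library, with replicates not pooled. The submitters' processing notes name HISAT2, DESeq2 and the genome build IRGSP-1.0, without roles or versions. The tool that made the FPKM values, the gene annotation and any use of strand are not given in the sources used here. FPKM values correct for gene length and for the total of mapped fragments, so a large change in a few abundant genes shifts the values of all others. Where fragments are counted whole, the ratio of 2 libraries at barely detected loci piles up at 1 value that gives their relative depth. Among loci between 0 and 0.1 FPKM in srl1-KO replicate 1 and another library, 3.39% to 4.97% fell into the fullest bin of width 0.01 on the log2 ratio. That bin held 47 to 74 loci, against a mean of 5.36 to 6.48 per bin over the range around it, the fullest bin included. This placed the depth of srl1-KO replicates 2 and 3 at 0.901 and 0.895 times, and of non-KO replicates 1, 2 and 3 at 0.889, 0.94 and 0.946 times, that of srl1-KO replicate 1. Most loci showed no such step and gene lengths were not matched, so whole fragments were not recovered. The absolute depth is unknown, and no counting interval or detection limit can be given. A count-based test was for that reason not used.

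The file lists 39477 loci, of which 35679 carry an identifier of the rice annotation (its first digits give the chromosome) and 3798 are loci named by the authors as new genes, called unannotated here. The file does not pair identifiers with gene names. The reference table used here, of the assembly ASM3414082v1, contained 1 of the identifiers, so names and product descriptions could not be attached to the loci, and coordinates are not printed because the builds differ. Names are used for the target and for 3 gene lists whose identifiers had been written down before the data were examined, from general knowledge of published rice gene assignments and without a source table. A further 5 leaf rolling names had no identifier in the form the file uses and were left out. For 16 of these 22 names the reference table places a gene of that name or synonym on the chromosome given by the identifier. All 15 pairs of such names on 1 chromosome stood in the same order in the identifiers and in the table. SRL1 and the other 4 names not found in the table (NRL1, COW1, REL2 and MYB103L) were used without this check. HB3 was dropped by a rule set in advance, because the table gives that name only on other chromosomes. A further 45 lists defined by product name could not be built. Among them were lignin synthesis, peroxidases, vacuolar proton pumps, photosynthesis, hormone response, defence and the cell type markers other than those of secondary-wall cells. Checks of GC content and gene length were void because no locus had a matched sequence or length.

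From the FPKM values, log2(FPKM + 1) was computed for the 19556 loci with a mean of at least 1 FPKM over the 6 libraries. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested loci and a threshold of 0.05 on the adjusted p. Every log2 change is srl1-KO minus non-KO on the log2(FPKM + 1) scale, which understates the change of low loci. Fold values are ratios of mean FPKM. Lists with at least 5 tested members were compared with all other loci by camera with a preset correlation of 0.01, by camera with an estimated correlation, and tested on their own by fry. Single genes were also compared by a two-sided exact permutation test, whose smallest possible p with 3 libraries against 3 is 0.1. The numbers 1 to 3 in the sample titles were not used as pairs. No pair of libraries held identical values.

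The rule for named genes was set before the data were examined. It took the target, any leaf rolling gene, and the loci with the largest changes that had a product name. From each list it took up to 3 members past the threshold with the smallest adjusted p, or else the most highly expressed member. All members of the cellulose synthase lists are given here, which goes beyond that rule. No locus had a product name, so only the 2 identifiers with the largest rise and the 2 with the largest fall are printed. They were taken among loci past the threshold with no overlap between genotypes and a mean of at least 5 FPKM in the higher genotype. The test was tried on simulated data with the same 19556 loci, means and spreads and 200 changed loci. It recovered 4% of loci changed by 0.5 on the log2 scale, 42% of those changed by 1, 78% of those changed by 2 and 100% of those changed by 3, with 50 loci of each size, and 5.08% of its calls were false. The data gave far more calls than the simulation (5321 against 118), and with more changed loci the same adjusted threshold is less strict. These rates may therefore understate what was recovered in the data. The alternatives tried were a pseudocount of 0.1 FPKM, no filter and a filter at a mean of 5 FPKM, rescaling to a sum of 1000000 per library, trimmed-mean (TMM) factors computed without weights on the FPKM values, quantile normalization, robust variance estimation, library weights, the replicate number as a block, and leaving out each library in turn.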

Results

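The transcriptome of mature rice leaves was measured in 3 libraries of an SRL1 knockout (srl1-KO) and 3 libraries of the control (non-KO). SRL1 (SEMI-ROLLED LEAF1) encodes a putative glycosylphosphatidylinositol-anchored protein known for its effect on leaf rolling. The comparison asks which genes differ in expression when it is knocked out. FPKM values summed to between 598611 and 628270 per library, and the number of loci at 1 FPKM or more was 19316, 19342 and 19330 in the srl1-KO libraries and 19053, 18861 and 18928 in the non-KO libraries. The relative depth read from barely detected loci differed little, at 0.889 to 0.946 times that of srl1-KO replicate 1 in the other 5 libraries, and the absolute depth is unknown. The 10 most abundant loci took 9.84% to 11.5% of the summed FPKM in srl1-KO and 8.49% to 9.56% in non-KO. The first principal component held 65.2% of the variance and separated the genotypes. Spearman correlations between libraries, taken across tested loci, ran from 0.936 to 0.964 within srl1-KO, from 0.951 to 0.957 within non-KO and from 0.846 to 0.864 between genotypes.

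SRL1 (Os07g0102300, chromosome 7) was expressed at a low level in both genotypes. Its level was 1.62, 2.22 and 1.96 FPKM in srl1-KO replicates 1, 2 and 3 and 2.50, 2.70 and 3.30 FPKM in non-KO replicates 1, 2 and 3. The mean was 1.93 ± 0.301 FPKM (SD, n = 3) in srl1-KO and 2.83 ± 0.416 FPKM (SD, n = 3) in non-KO, with no overlap between genotypes. The log2 change was -0.39 ± 0.15 (SE) and did not pass the threshold in limma (adjusted p = 0.107), though it did with quantile normalization (adjusted p = 0.0488). The two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. The transcript was still present in every srl1-KO library. A knockout made by a small change in the coding sequence can leave the transcript in place, so these levels do not settle the labels and say nothing of the protein.

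Expression differed between genotypes at 5321 of 19556 tested loci (27.2%; limma, adjusted p under 0.05). Of these, 2995 rose in srl1-KO and 2326 fell. The falls were larger, with a median log2 change of -1.17 among loci that fell and 0.72 among loci that rose. Among the called loci, 1364 fell and 862 rose by at least 1 on the log2 scale, and 177 fell and 36 rose by at least 3. Fewer loci rose than fell by at least 1 in each of the 17 settings of the fit that were run. The genotypes did not overlap at 9215 loci (47.1%), against 10% that chance gives, and all 5321 called loci were among them. Which direction held more calls was not stable. Rises made up 56.3% of calls with the FPKM values as deposited, 57.3% after rescaling to equal sums, 54.1% with quantile normalization and 42.3% with TMM factors, which moved the median log2 change of all loci from 0.11 to 0.01. With the values as deposited, falls also outnumbered rises without srl1-KO replicate 2 (1330 rises and 1613 falls), without srl1-KO replicate 1 (1737 and 1841) and without non-KO replicate 1 (1727 and 1840). Without non-KO replicate 2 the counts were 1955 rises and 1951 falls.

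Among called loci without overlap, the 2 largest falls and the 2 largest rises were as follows. Os08g0414500 was at 88.6 ± 12.5 FPKM (SD, n = 3) in non-KO and at 0.0753, 0 and 0 FPKM in the srl1-KO libraries, a log2 change of -6.44 ± 0.13 (SE; limma adjusted p = 1.02e-05). Os04g0301500 fell from 528 ± 98.6 to 7.84 ± 7.29 FPKM (SD, n = 3 each), a log2 change of -6.49 ± 0.86 (SE; limma adjusted p = 0.00291). Its srl1-KO values spread from 0.336 FPKM in replicate 3 to 14.9 FPKM in replicate 1. In the other direction, Os11g0690332 rose from 0.183 ± 0.0939 to 77.4 ± 41.1 FPKM (SD, n = 3 each), a log2 change of 5.94 ± 0.33 (SE; limma adjusted p = 0.000124). The unannotated locus Oryza_sativa_newGene_8375 rose from 0.148 ± 0.13 to 80.8 ± 39.1 FPKM (SD, n = 3 each), a log2 change of 6.06 ± 0.31 (SE; limma adjusted p = 0.000108). The values of these 2 rising loci ran side by side in each srl1-KO library (125 and 126, 55.7 and 60.8, 51.8 and 55.7 FPKM), and whether they are separate genes or 1 region counted under 2 identifiers cannot be read from the file, so both are reported as uncertain. What these 4 loci encode is not given in the files or table used here.

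Cellulose synthase genes of the primary wall were mostly lower in srl1-KO. CESA proteins are the catalytic subunits of the plasma-membrane complex that makes cellulose. Of the 5 primary-wall members measured, 3 fell, 1 rose and 1 did not pass the test, and the counts were the same when adjusted over the list alone. CESA5 (Os03g0837100) fell most, from 34.4 ± 4.45 to 1.96 ± 0.492 FPKM (SD, n = 3 each), a 17.5-fold difference (log2 change -3.59 ± 0.17 SE; limma adjusted p = 7.88e-05). CESA6 (Os07g0252400) fell from 12.8 ± 3.52 to 2.99 ± 0.114 FPKM, a 4.29-fold difference (log2 change -1.76 ± 0.19 SE; limma adjusted p = 0.0014). CESA1 (Os05g0176100) fell from 23.9 ± 3.26 to 14.9 ± 1.4 FPKM, a 1.6-fold difference (log2 change -0.64 ± 0.13 SE; limma adjusted p = 0.0145). CESA3 (Os07g0424400) rose from 6.49 ± 1.48 to 10.1 ± 0.349 FPKM, a 1.56-fold difference (log2 change 0.59 ± 0.16 SE; limma adjusted p = 0.0377). CESA8 (Os07g0208500) stood at 6.23 ± 1.75 FPKM in non-KO and 6.1 ± 1.43 FPKM in srl1-KO, and the 95% interval of its log2 change ran from -0.57 to 0.54.

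As a list, the 5 primary-wall genes were lower than other loci by camera with a preset correlation (adjusted p = 0.0371), with a median log2 change of -0.64 and a mean of -1.08. That call was lost with an estimated correlation (adjusted p = 0.168), with TMM factors (adjusted p = 0.0598) and without non-KO replicate 1 (adjusted p = 0.0944). Taken on their own, the 5 genes moved on balance downward by fry (adjusted p = 0.00199), a test that does not compare them with other genes. The falls of CESA5 and CESA6 passed the threshold in every setting run. The fall of CESA1 missed it without srl1-KO replicate 1 (adjusted p = 0.0516) and without srl1-KO replicate 2 (adjusted p = 0.0555). The rise of CESA3 missed it when any library other than non-KO replicate 1 was left out (adjusted p from 0.0662 to 0.118), with TMM factors (adjusted p = 0.073), with quantile normalization (adjusted p = 0.0538) and with no filter (adjusted p = 0.0648).

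**Figure D1:**
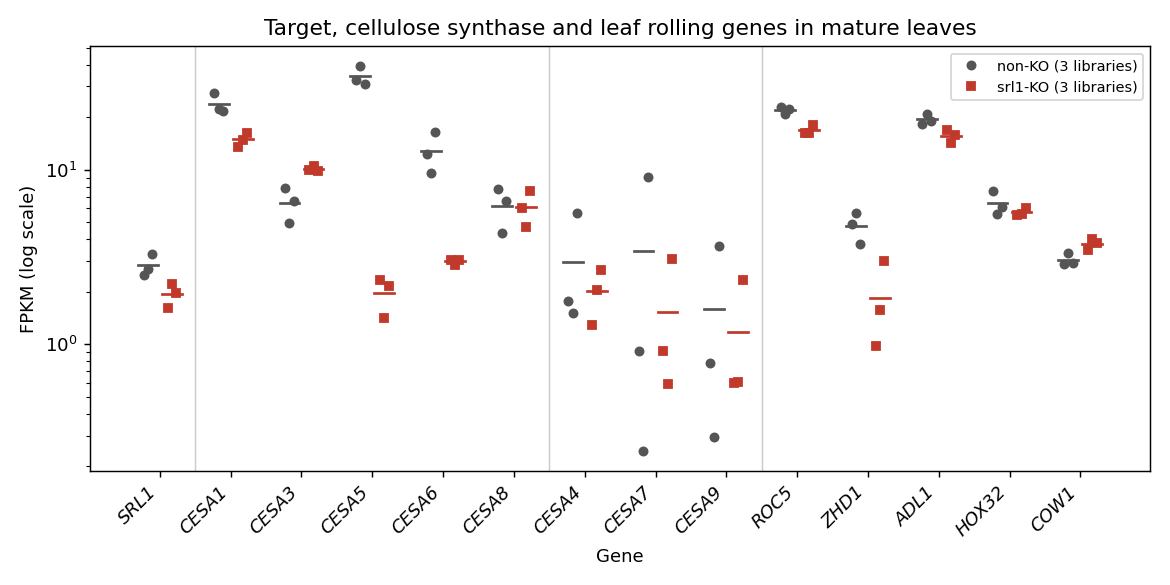
FPKM on a log axis in each library for SRL1, the primary-wall genes (CESA1, CESA3, CESA5, CESA6, CESA8), the secondary-wall genes (CESA4, CESA7, CESA9) and the tested leaf rolling genes, with circles for the 3 non-KO and squares for the 3 srl1-KO libraries and a line at each mean. CESA5 shows the widest gap, with means of 34.4 FPKM in non-KO and 1.96 FPKM in srl1-KO, while the secondary-wall genes overlap between genotypes.

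The secondary-wall cellulose synthases served as markers of cells with thickened walls, such as fibre and xylem cells. None of the 3 passed the test, and none did when adjusted over the list alone. CESA4 (Os01g0750300) was at 2.98 ± 2.31 FPKM in non-KO and 2.01 ± 0.694 FPKM in srl1-KO (SD, n = 3 each). CESA7 (Os10g0467800) was at 3.41 ± 4.91 and 1.53 ± 1.34 FPKM, and CESA9 (Os09g0422500) at 1.59 ± 1.83 and 1.18 ± 0.994 FPKM. All 3 were highest in replicate 3 of each genotype, where CESA7 reached 9.07 FPKM in non-KO and 3.06 FPKM in srl1-KO against 0.244 to 0.919 FPKM in the other 4 libraries. The 95% interval of the CESA7 log2 change, from -2.21 to 1.58, allows a large difference in either direction.

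Of 12 genes known from other work to affect leaf rolling or leaf polarity, 5 were expressed highly enough to be tested. ROC5 and ZHD1 fell, none rose, and 3 did not pass the test. Among all tested loci 27.2% were called, so this count does not by itself set the list apart. Adjusted over the list alone, ADL1 was also past the threshold, giving 3 falls. ROC5 (Os02g0674800), a homeodomain-leucine zipper factor that acts on bulliform cells, fell from 22.1 ± 1.15 to 16.8 ± 1.07 FPKM (SD, n = 3 each), a 1.31-fold difference (log2 change -0.37 ± 0.10 SE; limma adjusted p = 0.0341). ZHD1 (Os09g0466400), a zinc-finger homeodomain factor, fell from 4.77 ± 0.946 to 1.85 ± 1.05 FPKM, a 2.57-fold difference (log2 change -1.07 ± 0.28 SE; limma adjusted p = 0.0334). ADL1 (Os02g0709400), a calpain-type protease, was at 19.4 ± 1.28 FPKM in non-KO and 15.7 ± 1.27 FPKM in srl1-KO (limma adjusted p = 0.0836 over all loci, 0.0392 over all loci with TMM factors and 0.0487 over the list alone). HOX32 (Os03g0640800), a class III homeodomain-leucine zipper factor, was at 6.45 ± 1.02 and 5.72 ± 0.3 FPKM, and COW1 (Os03g0162000), a flavin monooxygenase of auxin synthesis, at 3.05 ± 0.253 and 3.77 ± 0.28 FPKM.

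The call of ROC5 was lost when any library other than srl1-KO replicate 3 was left out (adjusted p from 0.0547 to 0.12) and with quantile normalization (adjusted p = 0.053). That of ZHD1 was lost without srl1-KO replicate 1 or 2 or non-KO replicate 1 or 2 (adjusted p from 0.0762 to 0.103) and with no filter (adjusted p = 0.0672). The list did not stand apart from other loci by camera (adjusted p = 0.0903 with a preset and 0.168 with an estimated correlation). Fry, which does not compare them with other genes, found its 5 tested members lower on balance (adjusted p = 0.0128). With no filter on low values the list passed by camera (adjusted p = 0.0328, preset correlation). That setting took in all 12 members, 7 of them with a mean under 1 FPKM, among 32890 tested loci, so it is a different set. The locus written down as HB3 failed the name check and was kept out of the list, so its identity is uncertain. HB3 is the name of a class III homeodomain-leucine zipper gene. This locus was measured at 2.1 ± 0.115 FPKM in non-KO and 5.05 ± 0.723 FPKM in srl1-KO. It rose by 0.96 ± 0.14 on the log2 scale (SE, limma adjusted p = 0.00386). With it added, the leaf rolling list had an adjusted p of 0.377 by camera with the preset correlation. The other 7 list members had a mean under 1 FPKM and were not tested. Among these, CFL1 (Os02g0516400) was at 1.18 ± 0.331 FPKM in non-KO and 0.374 ± 0.246 FPKM in srl1-KO without overlap (two-sided exact permutation p = 0.1, the smallest possible). YAB1 (Os07g0160100) was at 0.808 ± 0.336 and 0.509 ± 0.149 FPKM and REL2 (Os10g0562700) at 0.939 ± 0.534 and 0.669 ± 0.266 FPKM. SLL1, NRL1, AGO7 and MYB103L had group means between 0.00193 and 0.201 FPKM.

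Called loci were found on all 12 chromosomes at similar shares of the loci tested, from 26.1% on chromosome 6 to 29.6% on chromosome 9. Their direction differed by chromosome. On chromosome 12, 219 loci rose and 62 fell, so that 77.9% of the calls were rises, and on chromosome 11, 200 rose and 84 fell (70.4%). Chromosomes 8 and 10 followed with 65.4% and 60.4% rises. On chromosome 3, 320 rose and 371 fell (46.3% rises), and on chromosome 5, 201 rose and 219 fell (47.9%). Chromosome 7, which carries SRL1, had 256 rises and 174 falls (59.5%). With TMM factors the share of rises was 63.5% on chromosomes 11 and 12 together and 39.9% on the others, against 74.2% and 54.0% with the values as deposited. Among the 604 tested unannotated loci, which were expressed at a median of 2.42 FPKM, 61 rose and 36 fell.

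**Figure D2:**
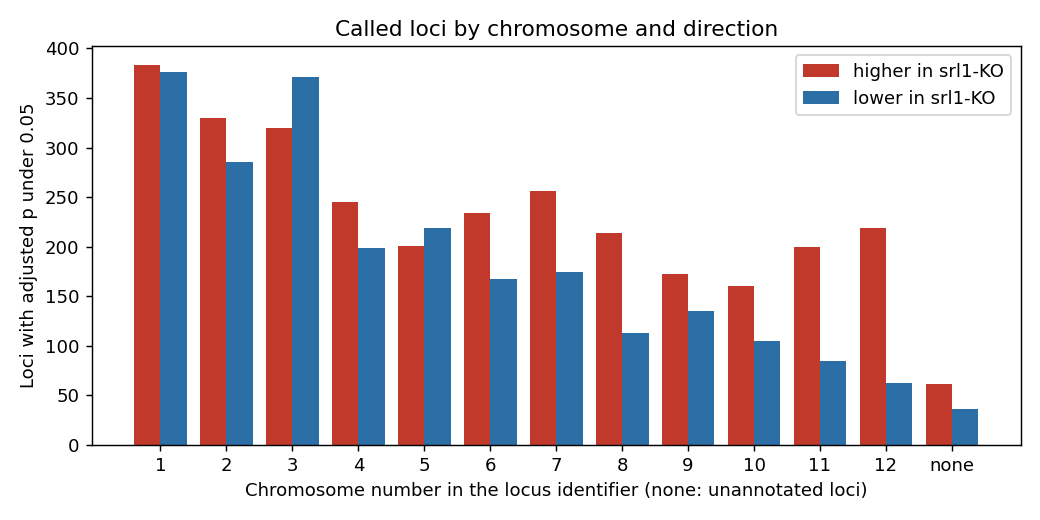
Number of loci past the threshold on each chromosome, read from the locus identifier, with unannotated loci under none; paired bars give loci higher and lower in srl1-KO from 3 libraries per genotype. Rises outnumber falls most on chromosome 12, with 219 against 62, and falls outnumber rises on chromosomes 3 and 5.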

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

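The tests on settings without unannotated loci and with HB3 were chosen after the data were seen; the others were planned. No locus called with the FPKM values as deposited changed sign in any of the 17 settings in which it was tested. Of the 5321 calls, 2607 stayed past the threshold with their direction in all settings counted. The filter at a mean of 5 FPKM was not counted because it tests fewer loci. The setting without unannotated loci was counted, so the 97 called unannotated loci, which it does not test, are not among the 2607. The total number of calls ran from 3649 with the replicate block to 6662 with library weights, and from 2943 to 4649 when 1 library was left out. Rises numbered 1765 with the replicate block and 1330 to 2547 without 1 library. Falls then outnumbered rises with the block (1884 falls) and without srl1-KO replicate 1 or 2 or non-KO replicate 1, as they did with TMM factors. With fewer libraries or residual degrees of freedom a lower count follows from the design. The labels do not say whether the shared numbers in the titles pair the libraries. The deviations of same-numbered libraries from their genotype means correlated at -0.05, 0.05 and 0.02, against -0.16 to 0.16 for different numbers, and 0 of the 6 libraries correlated best with their own number. The overlap of loci high in 1 library of each genotype points the other way, at 7.42 to 8.04 times that of independent lists for same numbers and 3.37 to 5.96 times for 5 of the 6 pairs with different numbers (11.3 times for the other), so whether the numbers mark anything shared stays open. The block moved the total from 5321 to 3649. SRL1 kept its direction throughout and passed the threshold only with quantile normalization (log2 change -0.50, adjusted p = 0.0488). It was not tested under the filter at 5 FPKM. The number of lists past the threshold, 1 of 2, became 2 with no filter and by fry. With no filter the leaf rolling list had an adjusted p of 0.0328 by camera, but there all 12 members were tested, also those with a mean under 1 FPKM. The number became 0 with TMM factors, with the replicate block and with an estimated correlation. Without 1 library it was 0 to 1. With the block, the primary-wall list (adjusted p = 0.0539) and CESA1, CESA3, ROC5 and ZHD1 missed the threshold (adjusted p = 0.0547, 0.0764, 0.0844 and 0.0764). The leaf rolling list with HB3 had an adjusted p of 0.377. Of the genes that were not called, the log2 change turned sign without 1 library for CESA8 (-0.22 to 0.14), CESA4 (-0.54 to 0.16), CESA7 (-0.92 to 0.58) and CESA9 (-0.50 to 0.43), so their direction is not determined; the 3 secondary-wall genes turned upward without non-KO replicate 3. The robust setting does not enter the list tests. The causes of the other changes were not tested. The absolute depth of the libraries is unknown. In the simulated data changes of 0.5 on the log2 scale were mostly missed, but far fewer loci were changed there than were called here.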

Other observations

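The tests of chromosome parts, of scaling and of replicate 3 were chosen after the results were seen. The direction of change followed the chromosome along most of the length of chromosomes 11 and 12. Of 40 windows of 50 consecutive tested loci on these chromosomes, 35 had a median log2 change above that of all tested loci, against 154 of 333 windows on the other chromosomes. This was not particular to chromosomes 11 and 12 (95% and 80% of windows), since chromosomes 7 and 10 had 79.3% and 73.7% of their windows above that median, while chromosome 3 had 31.4%. On chromosome 11 the share of rises among called loci was 67.7% before the midpoint of its tested loci and 72.8% after it, and on chromosome 12 it was 74.0% and 81.2%. The window with the lowest median lay on chromosome 1, at -0.39, and the one with the highest on chromosome 11, at 0.50.

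This chromosome pattern was noticed in the data and then tested on the same data, with bounds written before the tests of expression level and linked segments were run. A lower expression level of these loci was argued against. Matching on mean FPKM moved the median log2 change of the other chromosomes only from 0.10 to a median of 0.11 over 10000 sets. On chromosomes 11 and 12 it was 0.20, above the highest of these sets (0.15). That excess does not set these chromosomes apart, since they were picked for their rises and had the highest medians of the 12. The sets mixed loci of all other chromosomes and so held little of the spread between chromosomes. Chromosome 10 alone had a median of 0.16. The log2 gap from chromosomes 11 and 12 to the highest set was 0.0572. Picking these chromosomes for their rises may have enlarged that gap, so it does not decide on scaling between libraries. A single factor per library would move loci of the same level alike on every chromosome. With TMM factors the share of rises on chromosomes 11 and 12 stayed above that on the others. The difference was 23.6 points, against 20.2 with the values as deposited, so these factors did not remove it. A few linked segments alone would leave most windows with no lean to 1 side, yet 87.5% of the windows lay above the median of all tested loci. The lean therefore ran along most of these chromosomes. They were picked for their rises, however, and windows on other chromosomes leaned too, with 79.3% above on chromosome 7 and 35.2% on chromosome 1. Linked segments on top of such a lean are not excluded. The knockout itself and a difference between plant stocks or growth batches stay open and cannot be told apart, since the labels name no line or batch within a genotype, and GC content, gene length and gene families could not be examined here.

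Annotated loci switched fully between genotypes were few by the limits set here, which are not detection limits. Only 9 annotated loci were under 0.1 FPKM in every library of 1 genotype and at 5 FPKM or more in every library of the other, 8 of them expressed in non-KO and 1 in srl1-KO. The count depends on these limits, and Os11g0690332 missed them with 0.212 and 0.258 FPKM in non-KO replicates 1 and 2. A difference linked to the edited SRL1 locus, linked segments that differ between the plants compared, and reads shared between overlapping or duplicated neighbours could each give such loci. Of these, 0 lay among the 300 loci nearest SRL1, where the upper 95% exact limit of 1.22% is far above the 0.0254% found elsewhere. In identifier order, 0 had another such locus within 5 places, and random sets of called loci had a median of 0 as well, which left 0 neighbouring pairs to compare. With so few loci none of these explanations can be decided.

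The split of the 6 libraries by genotype gave 5321 calls, and the highest of the other splits into 3 and 3 gave 6; 1 of the 10 splits reached the real count. With 10 splits no share under 0.05 can be had. Every other split also mixes the genotypes in both groups, so any genotype difference adds to the spread within groups and lowers the calls. The contrast between the counts therefore does not measure what chance would give.

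The secondary-wall genes CESA4, CESA7 and CESA9 were highest in replicate 3 of both genotypes, which raised the question whether these libraries had more in common. Loci at least 2 times above both other libraries of their genotype numbered 40 in both replicate 3 libraries together, 34 for replicate 1 and 21 for replicate 2, against 5.39, 4.44 and 2.61 for independent lists. The excess of 7.42 times for replicate 3 was no larger than the 7.66 and 8.04 times for replicates 1 and 2. An excess was also found in all 6 pairs of libraries with different numbers. It was largest of all in srl1-KO replicate 1 with non-KO replicate 2, at 11.3 times, and smaller than in every same-numbered pair in the other 5, at 3.37 to 5.96 times. The 4 pairs that join a replicate 3 library to one of another number had 3.37 to 5.38 times, less than the replicate 3 pair itself. Whether the replicate 3 libraries had something in common therefore stays open.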
